A study of Zea mays with 12 samples.

How the data were processed

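RNA from maize (Zea mays) kernels and endosperm of reciprocal crosses between the inbred lines B73 and Mo17 was sequenced. With the mother written first, BxM stands for B73 pollinated by Mo17 and MxB for Mo17 pollinated by B73. Samples were whole kernels before pollination (0 days after pollination, DAP), whole kernels at 3 and 5 DAP, and endosperm at 7, 10 and 15 DAP. Each of the 12 combinations of cross and age has 1 library. The labels speak of replicate plant material for RNA extraction, but each combination was used here as the single column deposited for it.

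For each library the authors deposited a table of read counts over 108342 gene models and a second table of normalised signal. The submitters' processing notes name Bowtie and bedtools, with no versions, and the genome build and annotation release are not given in the sources used here. The headers of the count columns name B73, so reads from Mo17 alleles may map less well than reads from B73 alleles. Per the note deposited with the tables, the signal values were made by the authors with edgeR's trimmed mean of M-values (TMM) factors and scaled to RPM. Within each library the deposited signal was a constant multiple of the deposited counts, the implied factors lay between 0.598 and 1.47, and the signal columns were not used further. All tests ran on the deposited counts. Total counts ran from 59378582 to 70930121 per library at 0 to 10 DAP and were 35401314 (BxM) and 39864984 (MxB) at 15 DAP. These are sums over gene models and not reads, since overlapping models hold the same reads: 927 of the 41740 models with a summed count of at least 100 had counts identical to those of another model. A count of 0 allows up to 3 counts, which is 0.0423 to 0.0847 CPM (counts scaled to the library total) over the 12 libraries. This floor covers counting error only.

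Gene names came from a table of the Zm-B73-REFERENCE-NAM-5.0 assembly, which is not known to be the build of the files, so none of its coordinates are given. Of the model identifiers, 18731 matched a synonym there and 2591 of them had a usable symbol. Other models are named by their identifier.

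In the 15 DAP columns 21 models that are abundant at 10 DAP were listed at 0. They were found by a rule set after the data were seen: 0 in both 15 DAP libraries with a mean count of at least 5000 at 10 DAP (20 models), or 0 in one with at least 100000 in the other (1 model). They include the sucrose synthase gene sh1, the gamma-zein genes gz27 and gz16 and alpha-zein genes. They were left out of the tests that use 15 DAP, and no change to or difference at 15 DAP is given for them. In the tests of earlier age steps their listed zeros stayed in the fit of all 12 libraries.

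Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05). Changes between consecutive ages were fitted on all 12 libraries with age and cross as terms, which leaves 5 residual degrees of freedom. Crosses were compared in the 6 endosperm libraries with age as a term (2 residual degrees of freedom) and in the 4 kernel libraries of 3 and 5 DAP in the same way (1 residual degree of freedom). The p-values therefore measure how unequally the 2 crosses behave, not the spread between plants of the same cross. Standard errors (SE) of log2 fold changes were derived from the F statistic, and expression levels are CPM with TMM factors. Kernels and endosperm differ in tissue as well as age, so the step from 5 to 7 DAP compares both at once.

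The 14 gene lists were planned before the data were examined: starch synthesis, storage proteins, endosperm transcription factors, transfer layer, embryo-surrounding region, aleurone, cell cycle, core histones, Polycomb repressive complex, auxin synthesis, photosynthesis, embryo markers, ovule MADS-box genes and known imprinted genes. Lists planned by description were filled by name from the table above, and planned identifiers that it contradicted were replaced or left out. The lists hold 103 models. They were tested with limma 3.58.1's camera (preset correlation), with camera under an estimated correlation and with fry, adjusted over the lists of each comparison. The rule for named genes, also fixed before the data were examined, takes the 10 models with the largest fold change in each direction among those past the threshold, with a mean count of at least 100 over the libraries compared and the same direction in both crosses (or at each age for a comparison of crosses). Members of the fixed lists may be named as well.

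On simulated counts with 50 changed models per fold size, the 10 against 7 DAP test of 44366 models recovered 0% of 2-fold, 14% of 4-fold, 70% of 16-fold and 90% of 64-fold changes. The endosperm test of the crosses, on 34423 models, recovered 12%, 86%, 98% and 100%, and the kernel test, on 39321 models, 0%, 26%, 82% and 100%. Each test had 200 changed models. Unchanged models called in error numbered 4 in the 10 against 7 DAP test, 11 in the endosperm test and 11 in the kernel test. The changed models were drawn from those with a mean count above 100, so recovery at lower counts was not measured. Apart from these changes the simulated libraries shared the same mean profile, unlike the real ones. Alternatives were DESeq2 1.42.0, upper-quartile factors, no low-count filter, each library left out, other sets of libraries and terms, and other treatments of models with identical counts or listed at 0. Python 3.11.15 and pandas 2.3.3 were used for summaries. The maternal share of reads, parent-of-origin and allelic expression, and its change with age, which had been planned, need counts per allele and were not analysed here.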

Results

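The 12 libraries follow maize kernels and endosperm from before pollination to 15 DAP in 2 reciprocal crosses, with 1 library per cross and age. The title of the series places them in a study of imprinted genes and of how the mother governs the supply of nutrients to the endosperm, the triploid seed tissue that holds 2 maternal and 1 paternal genome copies. The ranks of all models correlated between the 2 crosses of an age at a Spearman rho (across models, which are not independent replicates) of 0.869 at 0 DAP, 0.866 at 3 DAP, 0.885 at 5 DAP, 0.923 at 7 DAP, 0.912 at 10 DAP and 0.887 at 15 DAP. All 108342 models entered, 41069 of them at 0 in every library, so rho is not that of expressed models alone. Counts at 15 DAP were more concentrated: the 100 most abundant models held 48.6% (BxM) and 41.3% (MxB) of the total, against 20.4% and 18.4% at 10 DAP. The totals and shares at 15 DAP include 20 models abundant at 10 DAP as 0. If those zeros are a fault, neither is directly comparable with 10 DAP.

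By 3 DAP, transcripts almost absent from unpollinated kernels had appeared in both crosses. GRMZM2G112792 went from 28 and 17 counts at 0 DAP (BxM and MxB) to 29201 and 19506 at 3 DAP (log2 fold change 10.48, SE 1.15, edgeR adjusted p = 0.0138), and GRMZM2G164090 from 15 and 11 to 13800 and 18632 (10.63, SE 0.903, adjusted p = 0.00578). NIP2-2, of the aquaporin family, had no counts at 0 DAP and 294 and 296 at 3 DAP, at least 130-fold higher (adjusted p = 0.037). Yucca6, of the flavin monooxygenases that make auxin, rose by a log2 of 3.08 (SE 0.36, adjusted p = 0.0174), and Opaque11, a bHLH regulator of endosperm, by 3.39 (SE 0.499, adjusted p = 0.0318) from levels of 0.02 and 0.10 CPM. HAK25, of a potassium transporter family, fell by 2.47 (SE 0.39, adjusted p = 0.037), and CDPK1, a calcium-dependent protein kinase, fell by 1.55 (SE 0.231, adjusted p = 0.0318). Of the 5 measured auxin synthesis members 1 rose, or 3 adjusted over the list alone (camera adjusted p = 0.000106, adjusted p = 0.0843 with an estimated correlation). No core histone member passed, with a list median of 0.96 (camera adjusted p = 0.0285, adjusted p = 0.739 with an estimated correlation). BxM at 3 DAP stood apart in that list, with all 10 members above MxB. Its member H4C7-a went from 85.9 to 415 CPM in BxM and from 120 to 162 in MxB. No storage protein member passed either (camera adjusted p = 0.00663, adjusted p = 0.748 with an estimated correlation), and its counts were traces. The zein gene fl2 went from 167 to 178 counts in BxM and from 2 to 144 in MxB, so the list's change rests on MxB at 0 DAP standing apart. In all, 246 models rose and 8 fell of 46342 tested, against 2809 and 803 with DESeq2. These counts rest on single libraries: 8 and 0 were called without BxM at 0 DAP, 20 and 1 without MxB at 0 DAP, 37 and 0 without BxM at 3 DAP, and 1613 and 1835 without MxB at 3 DAP. They were 140 and 6 without BxM at 5 DAP, 136 and 6 without MxB at 5 DAP, 190 and 3 without BxM at 7 DAP, 180 and 3 without MxB at 7 DAP, 157 and 2 without BxM at 10 DAP, and 143 and 2 without MxB at 10 DAP.

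Between 3 and 5 DAP only 6 models passed, all higher at 5 DAP. GRMZM2G348846 had no counts at 3 DAP and 321 and 300 at 5 DAP, at least 95.2-fold higher (edgeR adjusted p = 0.00661). GRMZM2G412075 rose by a log2 of 4.44 (SE 0.311, adjusted p = 0.00661), and GRMZM2G323925 by 6.08 (SE 0.607, adjusted p = 0.0326), together with the overlapping model AC203847.3_FG004, whose counts are nearly identical. No list member passed over all models, yet lists of the basal endosperm stood apart. The 3 genes of the embryo-surrounding region, the endosperm zone around the embryo, had a median log2 change of 6.36 and all 3 passed when adjusted over the list alone (camera adjusted p = 4.48e-05, adjusted p = 0.265 with an estimated correlation). The 8 genes listed for the transfer layer, the basal cells through which the endosperm takes up sugars and amino acids, had a median of 5.08, and 6 passed when adjusted over the list alone (camera adjusted p = 3.91e-05, adjusted p = 0.294 with an estimated correlation). Its members GRMZM2G144581 (16.3 and 16.5 CPM in BxM and MxB) and mn1 (9.87 and 26.0) stood highest before pollination. In these data they do not mark endosperm alone. The list of 10 core histones had a median of -1.32, and 8 were lower when adjusted over the list alone (camera adjusted p = 2.22e-05, adjusted p = 0.265 with an estimated correlation). Its size depends on the high BxM library of 3 DAP. The gene his2a1 went from 1262 to 313 CPM in BxM and from 710 to 386 in MxB. The storage protein list, at trace counts, had a median of -1.09 and no member passed (camera adjusted p = 0.000221, adjusted p = 0.431 with an estimated correlation). That change lies in BxM at 5 DAP alone, where the zein gene z1A1_6 went from 605 to 15 counts against 1399 to 1183 in MxB. With edgeR no model was called lower, 4624 had an unadjusted p under 0.05 in either direction, and DESeq2 called 926 higher and 666 lower. Without MxB at 3 DAP edgeR called 1131 and 182, without BxM at 3 DAP it called 0 and 0, and without MxB at 7 DAP 26 and 0. It called 15 and 0 without BxM or without MxB at 0 DAP, and 2 and 0 without BxM or MxB at 5 DAP or at 10 DAP.

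From 5 DAP kernels to 7 DAP endosperm, most listed endosperm transcription factors and basal endosperm genes rose, and the measured ovule MADS-box genes fell. Of 8 endosperm transcription factors 7 rose (camera adjusted p = 2.65e-06, adjusted p = 0.15 with an estimated correlation). They include nrp1 (log2 fold change 10.40, SE 0.964, adjusted p = 0.000353), the storage protein activator pbf1 (8.26, SE 0.952, adjusted p = 0.000755), and fl3, which went from 46.2 and 48.8 CPM to 8506 and 5275 CPM in BxM and MxB. In the transfer layer list 6 of 8 rose and GRMZM2G144581 fell by 5.50 (camera adjusted p = 0.0163, adjusted p = 0.371 with an estimated correlation), and meg1 rose by 7.08 (SE 1.18, adjusted p = 0.00327). All 3 embryo-surrounding genes rose, with esr2 up by 5.04 (SE 1.12, adjusted p = 0.0113). The list as a whole did not pass (camera adjusted p = 0.0556). The 3 measured ovule MADS-box genes, regulators of carpel and ovule, all fell (camera adjusted p = 0.000477, adjusted p = 0.15 with an estimated correlation): zag2 went from 330 and 287 CPM to 4.27 and 3.24 CPM. In the photosynthesis list 3 of 8 fell and cab-m1 rose (camera adjusted p = 0.0115, adjusted p = 0.216 with an estimated correlation), and lhcb5 fell from 17.3 and 8.71 CPM to 0.167 and 0.165 CPM (SE of the log2 change 0.525, adjusted p = 0.000264).

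Genes of growth and reserve synthesis also differed between 5 DAP kernels and 7 DAP endosperm. Of 14 starch genes 6 rose, with the transporter gene bt1 up by 7.61 (SE 1.13, adjusted p = 0.002) (camera adjusted p = 0.0183, adjusted p = 0.371 with an estimated correlation). The 7 DAP libraries lay apart in this list, with 13 of 14 members higher in MxB. The gene bt1 stood at 14.8 CPM in BxM and 174 in MxB. The gene bt2, not past the threshold, went from 12.9 to 2.74 CPM in BxM and from 14.7 to 22.6 in MxB. The sucrose synthase gene sus1 fell by 2.09 (SE 0.477, adjusted p = 0.013). Of 18 storage protein genes 4 rose, led by leg1 at 8.65 and dzs18 at 7.29 (camera adjusted p = 0.00113, adjusted p = 0.371 with an estimated correlation). In the cell cycle list 4 of 6 rose, with the cyclin gene cyc3 up by 3.26 (camera adjusted p = 0.00145, adjusted p = 0.28 with an estimated correlation), and 6 of 10 core histones rose (camera adjusted p = 0.00145, adjusted p = 0.216 with an estimated correlation). Of 7 embryo markers 4 rose, with the oleosin gene ole1 at 21.4 and 53.6 CPM in 7 DAP endosperm (camera adjusted p = 0.00742, adjusted p = 0.15 with an estimated correlation). In the list of known imprinted genes 4 of 5 rose (camera adjusted p = 0.00567, adjusted p = 0.216 with an estimated correlation), among them the Polycomb genes fie1 (4.60, SE 0.724, adjusted p = 0.00259) and mez1 (1.35, SE 0.42, adjusted p = 0.0458). These were the 2 of 5 Polycomb members that rose (camera adjusted p = 0.243). In the auxin list 3 of 5 rose (camera adjusted p = 0.0648), with yuc up by 6.63, and in the aleurone list 1 of 2, GRMZM2G091054, by 6.27 (camera adjusted p = 0.0648). Over all models 4635 rose and 6856 fell. Upper-quartile factors moved the median of all models by 0.20 and gave 5813 and 6136. The counts were 2141 and 4341 without BxM at 5 DAP, 2078 and 4307 without MxB at 5 DAP, 2546 and 3583 without BxM at 7 DAP, and 2246 and 3611 without MxB at 7 DAP.

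**Figure D1:**
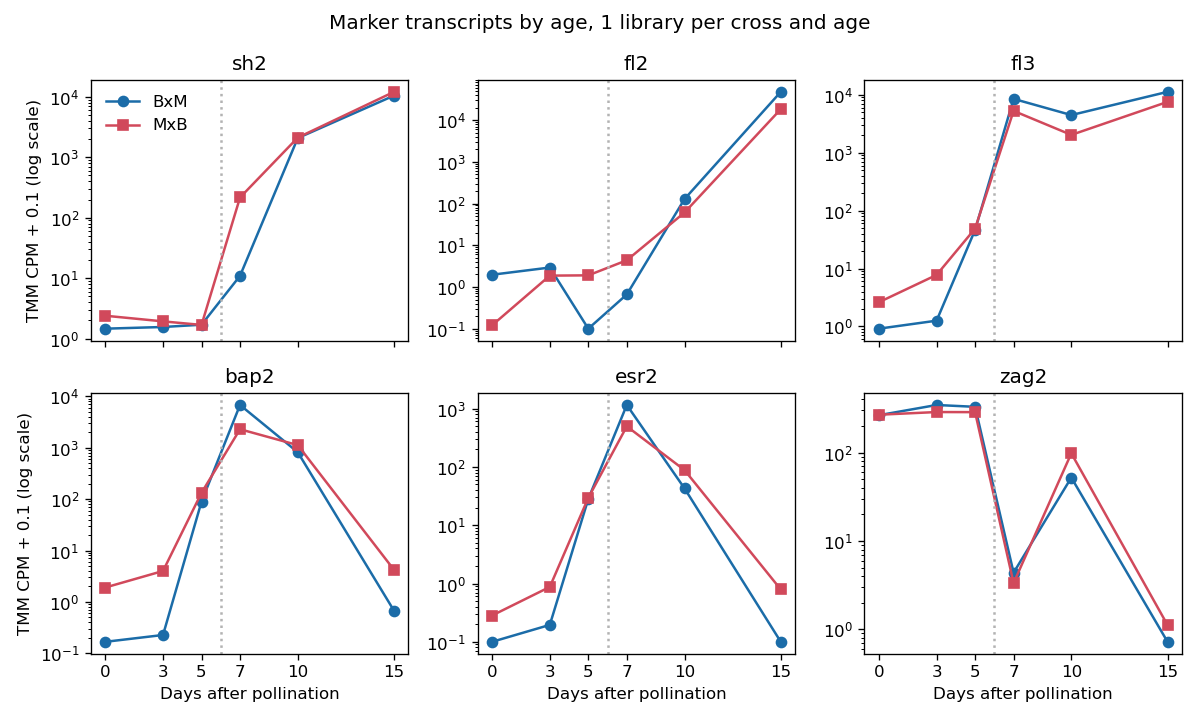
TMM-scaled CPM plus 0.1, on a log axis, against days after pollination for 6 genes of the fixed lists, with 1 point per library (circles BxM, squares MxB) and a dotted line between kernels and endosperm. The ovule gene zag2 stands at 330 and 287 CPM at 5 DAP and at 4.27 and 3.24 CPM at 7 DAP, and the starch gene sh2 at 10460 and 12070 CPM at 15 DAP.

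In endosperm between 7 and 10 DAP, most genes of starch synthesis rose. Of 14 measured, 10 rose and none fell (median log2 change 1.99, camera adjusted p = 8.2e-11, adjusted p = 0.135 with an estimated correlation). Both subunit genes of ADP-glucose pyrophosphorylase rose, bt2 by 6.34 (SE 0.854, adjusted p = 0.00973) and sh2 by 4.59 (SE 1.03, adjusted p = 0.0466), as did the granule-bound starch synthase gene wx1 by 6.17 (SE 1.16, adjusted p = 0.0255). The size of these rises depends on the cross, since the 7 DAP libraries lay apart. For bt2 the level went from 2.74 to 883 CPM in BxM and from 22.6 to 768 in MxB. For sh2 it went from 10.8 to 2075 and from 216 to 2112, and for wx1 from 0.80 to 401 and from 7.88 to 207. Of 18 storage protein genes 3 rose over all models and 17 when adjusted over the list alone (median 5.72, camera adjusted p = 2.93e-10, adjusted p = 0.301 with an estimated correlation), with gz27 up by 3.98 (SE 0.817, adjusted p = 0.0422) and bz15 by 6.36 (SE 1.01, adjusted p = 0.0155). Alpha-zein copies are near-identical, so their single values are uncertain. The zein activators o2 (5.57, SE 0.9, adjusted p = 0.0165) and pbf1 (3.81, SE 0.659, adjusted p = 0.021) were among 3 of 8 endosperm transcription factors that rose (camera adjusted p = 0.00234, adjusted p = 0.222 with an estimated correlation). The cell cycle list had 2 of 6 members lower, cyc1 and cyc3 (camera adjusted p = 0.0187, adjusted p = 0.454 with an estimated correlation). The embryo-surrounding list had a median of -4.27 with none of 3 past the threshold over all models and all 3 lower when adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.301 with an estimated correlation). AC148167.6_FG001 went from 1914 and 1064 counts to 0 in both libraries and stood at 2106 and 1577 at 15 DAP, so these zeros are doubtful and are not read as a decline.

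Transcripts of ovule MADS-box genes and of an embryo marker moved with this step as well. All 3 ovule MADS-box genes rose from 7 to 10 DAP (camera adjusted p = 2.53e-05, adjusted p = 0.135 with an estimated correlation), with zag2 at 52.1 and 98.1 CPM at 10 DAP. Of 7 embryo markers ole17 rose by 5.68 (SE 1.05, adjusted p = 0.0245), and 4 passed when adjusted over the list alone (median 3.16, or 2.95 with members at 0 taken at their bound, camera adjusted p = 0.00288, adjusted p = 0.135 with an estimated correlation). Among the models with the largest rise, the cell wall gene xet1 went from 4 and 0 counts to 2189 and 72, and GRMZM2G028129 from 94 and 68 to 17339 and 27478 (8.25, SE 0.823, adjusted p = 0.00408). No aleurone, Polycomb, auxin, photosynthesis or core histone list passed, nor did the transfer layer list (camera adjusted p = 0.742). Its median was -2.05, with bap2 at -2.68 and betl1 at -2.46 not past the threshold, while GRMZM2G144581 rose by 3.75 (SE 0.707, adjusted p = 0.0259). In the known imprinted list nrp1 rose by 3.05 (SE 0.675, adjusted p = 0.0453). In all 1311 models rose and 446 fell, against 3663 and 2267 with DESeq2 and 2272 and 1029 with the endosperm libraries alone, a setting chosen after the data were seen. Without BxM at 7 DAP the counts were 94 and 11, without MxB at 7 DAP 196 and 58, without BxM at 10 DAP 583 and 32, and without MxB at 10 DAP 297 and 34. Without a library of 5 DAP they were 875 and 287 (BxM) or 857 and 283 (MxB), and without a library of 0 DAP 949 and 284 (BxM) or 944 and 277 (MxB).

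From 10 to 15 DAP, transcripts of the transfer layer fell to near absence in both crosses. All 8 measured genes of the list fell, GRMZM2G144581 among them (median log2 change -9.72, camera adjusted p = 7.47e-06, adjusted p = 0.204 with an estimated correlation). The cell wall invertase gene mn1 went from 936 and 1293 CPM to 0.57 and 0.29 CPM (-11.38, SE 1.14, adjusted p = 0.000703), and bap2 from 819 and 1125 CPM to 0.57 and 4.10 CPM. All 3 embryo-surrounding genes fell (camera adjusted p = 0.0288, adjusted p = 0.242 with an estimated correlation), and esr2 fell by 7.62 (SE 1.34, adjusted p = 0.00596). Of the aleurone genes GRMZM2G091054 fell by 6.45 and vpp1 fell by 4.64 (camera adjusted p = 0.0289, adjusted p = 0.204 with an estimated correlation). All 6 cell cycle genes fell (camera adjusted p = 2.88e-05, adjusted p = 0.206 with an estimated correlation), and the replication clamp gene pcna2 fell by 3.81 (SE 0.406, adjusted p = 0.000868). Of 10 core histones 7 fell (camera adjusted p = 8.62e-05, adjusted p = 0.204 with an estimated correlation). Beside these groups, all 3 ovule MADS-box genes fell as well (camera adjusted p = 0.000186, adjusted p = 0.204 with an estimated correlation), with zag2 at 0.62 and 1.02 CPM at 15 DAP and a list median of -6.50, or -4.78 with members at 0 taken at their bound. Of 7 embryo markers 3 fell, or 5 adjusted over the list alone (camera adjusted p = 0.181, fry adjusted p = 0.0164), and vp1 fell by 4.95 (SE 1.05, adjusted p = 0.016). Among the models named by the rule, GRMZM2G141473 went from 2570 and 6759 counts to 0 and 0, at least 649-fold lower, and its 10 DAP mean lies little below the 5000 counts from which zeros at 15 DAP were set aside.

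Most measured storage protein transcripts and some starch transcripts rose over the same step. Of the 10 storage protein genes measured at both ages 7 rose (median 6.68, camera adjusted p = 6.33e-07, adjusted p = 0.204 with an estimated correlation). The alpha-zein gene fl2 went from 128 and 60.8 CPM to 47480 and 18290 CPM (8.43, SE 2.33, adjusted p = 0.0374), and z1C1_12 rose by 11.83 (SE 0.996, adjusted p = 0.00153). Of 13 starch genes 5 rose, with wx1 up by 5.27 (SE 1.08, adjusted p = 0.0115) and zpu1 by 4.70 (SE 0.437, adjusted p = 0.000601) (camera adjusted p = 9.19e-06, adjusted p = 0.204 with an estimated correlation). In the same list sus1 fell by 4.99 (SE 0.545, adjusted p = 0.000942). Among the transcription factors o2 rose by 2.81 (SE 0.77, adjusted p = 0.0367) and 7 of 8 did not pass (camera adjusted p = 0.0757). In the known imprinted list meg1 fell by 9.65 and 4 of 5 did not pass. The auxin, Polycomb and photosynthesis lists did not pass, though Yucca3 (at least 10.1-fold, adjusted p = 0.0313) and lhcb7 (at least 3.05-fold, adjusted p = 0.00501) fell to 0 counts. In all 1726 models rose and 6464 fell. Under upper-quartile factors, which moved the median of all models from -0.37 to -0.08, the counts were 2634 and 4787, with DESeq2 4333 and 7309, and with the endosperm libraries alone 3840 and 6118. Without MxB at 10 DAP they were 447 and 3188, without BxM at 10 DAP 545 and 4114, without BxM at 15 DAP 620 and 3334, and without MxB at 15 DAP 1016 and 4189.

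The kernels of 3 and 5 DAP still hold maternal ovary tissue, and the crosses differ there in the strain of the mother. Of 40879 models 1649 were higher in BxM and 1490 in MxB. Many were present in kernels of a B73 mother and absent from those of a Mo17 mother, or the reverse. GRMZM2G031087 had 1313 and 995 counts in BxM at 3 and 5 DAP and none in MxB, at least 437-fold higher (edgeR adjusted p = 0.00134), and GRMZM2G067929 had 509 and 1352 against none. In the other direction GRMZM2G365259 had no counts in BxM and 1692 and 1123 in MxB, at least 416-fold higher in MxB (adjusted p = 0.00134), and GRMZM2G419421 had none against 1494 and 1257. Before pollination, GRMZM2G031087 stood at 802 counts in the B73 mother and 0 in the Mo17 mother, and GRMZM2G365259 at 0 and 2673. Of the models higher in BxM that were kept in the fit of all ages, 98.6% were also higher in the B73 mother at 0 DAP, and of those higher in MxB 97.8% were also higher in the Mo17 mother, against 49.1% higher in B73 over 28096 models with a mean kernel count of at least 100. List members differed rarely: the histone gene his2b5 was higher in BxM (5.51, SE 1.18, adjusted p = 0.021), as was ohp1 (2.38, SE 0.53, adjusted p = 0.0246), and GRMZM2G091054 of the aleurone list was higher in MxB (-2.20, SE 0.576, adjusted p = 0.0486). Counts of GRMZM2G091054 in BxM and MxB were 6 and 165 before pollination, 28 and 313 at 3 DAP, and 1906 and 4633 at 5 DAP. Part of its difference at 3 DAP may therefore be traces. The storage protein list was lower in BxM with none of 16 members past the threshold (camera adjusted p = 0.000998, adjusted p = 0.958 with an estimated correlation), at trace counts. Its median log2 ratio of BxM to MxB was 3.10 at 0 DAP, -0.70 at 3 DAP and -4.12 at 5 DAP, so the difference comes mostly from BxM at 5 DAP. No other list passed. The test rests on 1 residual degree of freedom, and without a low-count filter it called 2536 and 2538.

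In endosperm, where both genomes are present, 2 of 35482 models passed the same test, both higher in BxM. The small count does not show that the crosses were alike, since the test recovered 12% of simulated 2-fold changes. Of the models called higher in BxM kernels, 584 with a mean endosperm count of at least 100 had a median log2 ratio of BxM to MxB of 0.91 in endosperm, and 454 of those higher in MxB kernels had one of -0.88. GRMZM5G871471 had 2001, 864 and 1003 counts in BxM at 7, 10 and 15 DAP against 0, 1 and 0 in MxB (log2 difference 11.62, SE 0.533, edgeR adjusted p = 0.00219), and GRMZM2G170309 had 2117, 1183 and 426 against 0, 2 and 0 (10.77, SE 0.579, adjusted p = 0.00343). Both had at most 4 counts in either unpollinated mother. Genes known to be imprinted in maize endosperm showed log2 differences of 0.81 for mez1 (SE 0.173, adjusted p = 0.193), 0.36 for fie1 (SE 0.187, adjusted p = 0.537), 0.33 for meg1 (SE 0.527, adjusted p = 0.858), 0.15 for nrp1 (SE 0.542, adjusted p = 0.941) and -0.32 for fie2 (SE 0.288, adjusted p = 0.723), none past the threshold over all models. Adjusted over the list alone, 1 of 5 was higher in BxM. Total counts do not tell maternal from paternal reads, so these values neither show nor exclude imprinting. No list passed, the smallest camera adjusted p being 0.273 for the cell cycle list. No model was called higher in MxB by edgeR, while 3873 models had an unadjusted p under 0.05 in either direction and DESeq2 called 682 higher in BxM and 409 in MxB. The counts were 456 and 249 without BxM at 7 DAP, 458 and 230 without MxB at 7 DAP, 30 and 10 without BxM at 10 DAP, 35 and 10 without MxB at 10 DAP, 0 and 0 without BxM or without MxB at 15 DAP, and 204 and 85 from 10 and 15 DAP alone, the last setting chosen after the data were seen.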

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

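All tests in this part, the interaction included, were chosen after the results were seen. The difference between the crosses was not the same in kernels and endosperm: an interaction term on the 10 libraries of 3 to 15 DAP called 773 of 44603 models, 352 with a larger and 421 with a smaller BxM to MxB ratio in endosperm.

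At 7 DAP the storage protein genes stood higher in MxB and the basal genes higher in BxM, and at 10 DAP both had turned. The median log2 ratio of BxM to MxB in the storage protein list was -2.77 at 7 DAP, 1.14 at 10 DAP and 0.33 at 15 DAP, and in the starch list, with a smaller swing, -0.71, 0.42 and 0.16. In the endosperm transcription factors it was -0.66, 0.80 and 0.32, and in the embryo markers -0.54, 0.89 and -0.20. In the transfer layer list it was 1.54, -0.95 and -2.07, and in the embryo-surrounding list 1.22, -1.04 and -1.97, where the 15 DAP values rest on few counts. These turns between ages compare single libraries and were not tested. At 7 DAP some storage protein counts, such as those of z1C1_4 (12 in BxM and 733 in MxB), were near the traces in kernels. For z1C1_4 those were 217 and 21 at 0 DAP and 202 and 349 at 3 DAP. Counts of gz27 (22684 and 116094) and leg1 (17279 and 75638) at 7 DAP were well above traces. In kernels the list ratio was 3.10 at 0 DAP and -4.12 at 5 DAP, so traces alone gave ratios as large as that at 7 DAP.

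Dilution of starchy endosperm by other tissue in the BxM library of 7 DAP would lower its genes alike. The median log2 ratio of MxB to BxM over all 32 starch and storage members lay 1.95 above that of the endosperm transcription factors (bootstrap 95% interval over members, not over libraries, 0.056 to 3.11). The storage list alone lay 2.11 above (1.20 to 3.36), at low counts for many of its members, and the starch list 0.05 above (-1.06 to 2.64), so dilution stays open. A candidate explanation is that MxB endosperm of 7 DAP was further along in development. The models for its test were filtered on the 7 DAP libraries compared. They had a mean 7 DAP count of at least 100. Their higher 7 DAP level exceeded 20 times the storage protein trace in kernels, scaled to their 15 DAP level. This left out fl2, wx1, bt2 and bz15. Of the models kept, 292 rose at least 4-fold from 10 to 15 DAP in both crosses. Their median log2 ratio of MxB to BxM at 7 DAP was 0.148 (bootstrap 95% interval 0.0478 to 0.239). It was -0.0275 in 2525 kept models that fell. The lead is smaller than the 0.5 asked of it. With such starch and storage genes left out the test cannot decide, so this explanation stays open. The cross itself and the hour of harvest stay open too, since each is a single library.

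AC148167.6_FG001 was listed at 0 in both 10 DAP libraries and at 799 to 3278 counts in the other 10, and whether the zeros are a fault of the file was not tested.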

How the results depend on the processing

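Which models are called depends strongly on the test and on single libraries. Leaving out at least 1 of the libraries ended the call of 19 of 19 named genes (3 against 0 DAP), 6 of 6 (5 against 3), 29 of 74 (7 against 5), 35 of 43 (10 against 7), 23 of 67 (15 against 10) and 2 of 2 (crosses in endosperm). None changed sign in the settings that tested it. Numbers are models higher and lower. With DESeq2 the counts were 2809 and 803 (3 against 0 DAP), 926 and 666 (5 against 3), 3663 and 2267 (10 against 7), 4333 higher (15 against 10) and 682 and 409 (crosses in endosperm). With upper-quartile factors 2634 rose at 15 DAP. Without a low-count filter they were 380 and 13 (3 against 0), 19 higher (5 against 3), 508 and 342 (crosses in endosperm) and 2536 and 2538 (crosses in kernels). With no cross term 143 rose at 3 DAP, and 845 and 295 changed at 10 DAP. Without the 0 DAP libraries 11 rose at 5 DAP, and 866 and 268 changed at 10 DAP. With 3 to 15 DAP the crosses in endosperm gave 0 and 1, and the 2 named genes did not pass the low-count filter. Settings chosen after the data were seen gave 560 and 39 (3 against 0) and 11 higher (5 against 3) with a cross term for each tissue, 2272 and 1029 (10 against 7) and 3840 higher (15 against 10) with endosperm libraries only, and 204 and 85 for the crosses at 10 and 15 DAP. Counting identical models once, and keeping or dropping the models listed at 0, moved no count by over 1.5 times. Leaving out each library gave 8 to 1613 and 0 to 1835 (3 against 0), 0 to 1131 and 0 to 182 (5 against 3), 2078 to 5322 and 3583 to 7125 (7 against 5), 94 to 1485 and 11 to 587 (10 against 7), 447 to 2411 and 3188 to 6786 (15 against 10), and 0 to 458 and 0 to 249 (crosses in endosperm). A library left alone at its age was assumed to vary like the others, and the kernel comparison of crosses would keep 0 residual degrees of freedom, so no test was run there. With an estimated correlation camera called 0 lists in each comparison. Fry called 1 list at 3 DAP, 4 at 10 DAP and 0 in the kernel comparison of crosses. Elsewhere similar numbers held different lists. Fry did not call the transfer layer list at 5 DAP (fry adjusted p = 0.108) or 7 DAP (0.148), or core histones at 5 DAP (0.0602). Nor did it call storage proteins at 5, 7 or 10 DAP (0.387, 0.0717 and 0.06). At 5 DAP it called the aleurone and auxin lists (0.0226 each), which camera did not, and the embryo-surrounding list (0.0307), which camera did. For settings that differ in models tested or libraries part of this follows from their construction, and otherwise the cause was not tested. Settings intended for allele counts (maternal share, parent of origin, allelic expression and its change with age) were not run. The crosses are paired by age in the fits above, and no block for replicate number was fitted because each cross and age has 1 column. By the simulation, 14% of 4-fold and 70% of 16-fold changes were recovered from 7 to 10 DAP, the only age step simulated.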

Other observations

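Models that only 1 of the mothers expressed before pollination give a view of gene dosage in the endosperm. In the unpollinated kernels 217 models had at least 200 counts in B73 and at most 1 in 100 of that in Mo17, with a mean endosperm count of at least 100, and 200 models met the mirrored rule for Mo17. In kernels of 3 and 5 DAP the B73 models had a median log2 ratio of BxM to MxB of 5.74 and the Mo17 models of -5.43. The hypothesis, written before these values were computed, was that in endosperm, with 2 maternal copies and 1 paternal copy, the ratio would be near 1 and -1. The medians were 1.05 (bootstrap 95% interval over models 0.98 to 1.13) and -0.986 (-1.04 to -0.872), near the ratios given by copy number. These intervals measure the spread over models that share the same 6 endosperm libraries, not the spread over libraries or plants. At 7, 10 and 15 DAP singly, the medians were 0.97, 1.30 and 1.00 for the B73 models and -0.89, -1.14 and -1.04 for the Mo17 models. Over 17249 models expressed at similar levels by both mothers the endosperm median was -0.05. Of the B73 models 158 of 217, and of the Mo17 models 123 of 200, lay within 0.5 of the copy number ratio. Remaining maternal tissue would move both medians outward and poorer mapping of Mo17 reads was not separated from this.

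The tests in the rest of this part were chosen after the results were seen. The 2 models called between the crosses in endosperm came from the real split of the 6 libraries, and the highest of the other splits gave 0. With 10 splits, of which 1 gave as many, no share under 0.05 can be reached.

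The models listed at 0 at 15 DAP include 9 named zein and sh1 models, models with nearly their counts, and others with no symbol, such as GRMZM2G346884. A candidate explanation is that counts of 1000000 or more are missing from these columns. The highest count in any library was 992970, 21 counts at 15 DAP were at 500000 or more, and GRMZM2G518465 stood at 903934 in BxM and 0 in MxB. Storage protein counts in kernels are low and gave a further test. At the median rate of 9 storage protein genes between their mean count in the 6 kernel libraries and that at 15 DAP, the 20 models listed at 0 in both libraries would have a median of 2.82e+06 counts (1.01e+06 to 6.17e+07). For 2 of them, sh1 and GRMZM2G090974, whose kernel counts run alongside, the implied count exceeds the total of a 15 DAP library, so their kernel counts are not traces. Without them the median was 2.06e+06. A real loss stays open: kernel counts spread by a log2 SD of 2.34 against 10 DAP levels and 0.776 against 15 DAP levels, a ratio of 3.01 where a ratio above 2 was set to count against it. With 1 gene left out at a time the ratio stayed above 2 (2.25 to 4.33). As the earlier form below had disagreed, the check was then widened to leaving out 3 of the 9 genes, and the ratio stayed above 2 in 78 of 84 sets (1.08 to 12.2). The kernel counts are low, down to a mean of 6.5 per library, and this test replaced an earlier form on libraries chosen for their zein counts, which gave a lower implied median and spreads too alike to decide, so its outcome depends on the genes and libraries used.

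The loss of transfer layer transcripts at 15 DAP cannot come from dilution by storage transcripts alone, since the list median of -9.716 lies far below the median of all models, -0.37. Another candidate explanation is that outer layers and embryo were kept with the endosperm at 10 DAP and left off at 15 DAP. That needs aleurone, ovule and embryo genes to fall as well. The smallest fall among these 3 list medians was -3.29, in the embryo markers. That list was not called by camera (adjusted p = 0.181) but was by fry (adjusted p = 0.0164). Of its 7 members 5 were lower when adjusted over the list alone. Lists not chosen to mark these tissues also fell, with medians of -3.905 for cell cycle and -3.84 for core histones. That is further than the embryo markers. It is less far than the aleurone list (-5.546) and the ovule list (-6.495, or -4.776 with members at 0 taken at their bound). With lists of other genes falling too, and 1 library per cross and age, the falls cannot single out this explanation. A change of the tissue with age predicts the fall of basal genes too, was not tested, and stays open.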
